A study of Nakaseomyces glabratus with 16 samples.

How the data were processed

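RNA was sequenced from Candida glabrata strain ATCC2001 (now Nakaseomyces glabratus), a pathogenic yeast, after 60 min at 37 °C in 4 conditions. Cells from M199, a defined tissue culture medium, were moved to fresh M199 at pH 4 or pH 8. Cells from YPD, a rich yeast medium, were moved to YPD with or without GSNO (S-nitrosoglutathione, a nitric oxide donor), whose concentration the labels give as 0.6 M. Per the labels, replicates 1 to 3 of each condition were selected for polyA RNA and sequenced paired-end with strand information. Replicate 4 of each condition was made without polyA selection and sequenced single-end without strand information. The series text calls the replicates biological.

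Per the submitters' processing notes, TopHat2 2.0.6 and HTSeq were used. The genome build, the annotation and the settings of both tools are not given in the sources used here. The deposited tables hold read counts per feature, whole numbers that the authors did not normalize, and RPKM values. In each library the deposited RPKM values were proportional to the counts divided by a feature length, and all 5234 lengths recovered in this way lay within 0.01 of a whole number. The median length was 1886 bases and 31.6% of the lengths were multiples of 3, so the lengths were not those of coding sequences alone. The denominators behind the deposited RPKM values exceeded the summed counts. The counted share was 95.8% to 97.5% in the polyA-selected libraries, 60.6% and 60.0% in the unselected M199 libraries at pH 4 and pH 8, and 82.9% and 82.6% in the unselected GSNO and YPD libraries.

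The table lists 5292 features, of which 5232 have an ID starting with CAGL0, 49 with Novel_proteincoding and 11 with CaglfMp. None of these IDs (0 of 5292) was found in the reference gene table used here (assembly GCF_010111755.1 of NCBI RefSeq, 5508 genes), and the files do not pair IDs with names. Features are therefore given by ID, with at most 2 higher and 2 lower per comparison. Further features named outside this rule were chosen after their values were seen, and are described as such. Of 32 gene lists fixed before the data were examined, 1 could be matched, the mitochondrially encoded features with the prefix CaglfMp, and none of its 11 members passed the count filter in the polyA-selected libraries. The planned set tests were therefore not run on these lists. A pair of sets was added after the IDs were seen: the newly annotated features (prefix Novel_proteincoding) and the features within 10 of a chromosome end in the order of the serial numbers in their IDs.

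Counts were tested with edgeR 4.0.16 in R 4.3.3 over the 12 polyA-selected libraries, with 1 mean per condition. TMM factors, filterByExpr, dispersion estimation and the quasi-likelihood F test were used, and p-values were adjusted by the Benjamini-Hochberg method over the 5150 features that passed the filter. A feature was called at an adjusted p under 0.05, and the number that also changed at least 2-fold is given beside each count. The residual degrees of freedom were 8, and the biological coefficient of variation was 0.087. The standard error of a log2 fold change is its absolute value divided by the square root of F. The comparisons were pH 8 with pH 4, GSNO with none, M199 pH 4 with YPD, the difference between the pH effect and the GSNO effect, and unselected with polyA-selected libraries (16 libraries, condition as a covariate). Set tests used camera in limma 3.58.1 with a preset correlation of 0.01. Levels in the polyA-selected libraries are CPM (counts of a feature for every 1000000 counts of its library) on TMM-scaled totals, with the SD over 3 replicates.

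The named features were the 2 with the largest change in each direction among those called, changed at least 2-fold, without overlap between the 3 and 3 libraries, and with a mean CPM of at least 10 in 1 of the groups. The rule, the comparisons and most alternatives were fixed before the data were examined. The alternatives were DESeq2 1.42.0 and its size factors, no filter, a stricter filter (CPM of at least 10 in 3 libraries), the replicate number as a block, only the 6 libraries compared, all 16 libraries with a library term, limma on log2(RPKM + 1) and log2(RPKM + 0.1) from the deposited RPKM values, counts thinned to the smallest library, and leaving out each replicate.

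On simulated counts for the 5150 features, 200 of which were changed, edgeR recovered 88.1% of 1.5-fold, 97.0% of 2-fold and 100% of 4-fold changes in the pH comparison, and 94.0%, 95.5% and 100% in the GSNO comparison. In each, 9 of 4950 unchanged features were called. The simulation changed few features, in both directions, around a level shared by all conditions, with the spread of the same fit. In the real pH and GSNO comparisons 66.6% and 86.2% of the features were called. It therefore does not test the scaling between libraries when most features change. No 2 libraries of a condition agreed within sampling noise: the chi-square per degree of freedom between replicates ranged from 1.92 to 110. Binomial intervals are exact (Clopper-Pearson, 95%) and, like the limit of 3 counts set for a count of 0, cover counting error only. Reads of near-identical or overlapping features could not be separated from the tables, and in the libraries without strand information neither could reads of opposite strands.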

Results

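Transcript levels of C. glabrata were compared between acidic and alkaline M199 and between YPD with and without GSNO, 60 min after transfer. The series holds 16 libraries: 3 polyA-selected replicates and 1 unselected replicate in each of 4 conditions. Summed counts ranged from 9662292 to 19380330 in the polyA-selected libraries and from 8576458 to 10723626 in the unselected ones. Within conditions the polyA-selected libraries correlated at r = 0.982 or above across features. In M199 pH 4, replicate 3 correlated at 0.985 and 0.982 with replicates 1 and 2, which correlated at 0.997 with each other. Between conditions the median r was 0.877 for M199 pH 4 with pH 8, 0.826 and 0.815 for GSNO with M199 at pH 4 and pH 8, and 0.657 for GSNO with YPD. YPD stood furthest from M199, with a median r of 0.489 for pH 4 and 0.625 for pH 8.

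The first question was which transcripts responded to the shift from pH 4 to pH 8. CAGL0G06798g rose 138-fold, from 10.1 ± 1.24 CPM (SD, n = 3) at pH 4 to 1390 ± 11.3 CPM at pH 8 (log2 fold change 7.11, SE 0.113, edgeR adjusted p = 2.12e-13). CAGL0F01485g rose from 0.588 ± 0.156 to 84.3 ± 3.77 CPM (log2 7.15, SE 0.173, adjusted p = 5.18e-12). CAGL0M01166g fell 419-fold, from 2628 ± 158 CPM at pH 4 to 6.26 ± 0.603 CPM at pH 8 (log2 -8.71, SE 0.0974, adjusted p = 2.87e-14). CAGL0J06028g fell from 96.6 ± 12.5 to 0.808 ± 0.342 CPM (log2 -6.89, SE 0.167, adjusted p = 5.18e-12). Among the 5150 features tested, 1710 were higher and 1719 lower at pH 8 (792 and 746 in a fit of all 16 libraries), and the median change of the called features was 0.55 on the log2 scale in absolute value. At least 2-fold changes numbered 363 higher and 435 lower, and at least 16-fold changes 12 higher and 42 lower. The unselected pH 8 and pH 4 libraries held 62 counts and 1 count of CAGL0F01485g (117 and 1.54 CPM). CAGL0M01166g had 8 and 19 counts there (15.0 and 29.3 CPM), against 6.26 and 2628 CPM in the polyA-selected libraries. A fall of CAGL0M01166g of that size was thus not seen in the unselected pair. CAGL0G06798g and CAGL0J06028g had 0 counts in both unselected libraries.

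Among the newly annotated features, 24 fell and 11 rose at pH 8, and 12 of the 47 tested did not pass the test. Adjusted over the list alone, 25 fell and 11 rose. The list as a whole lay lower than the other features (camera adjusted p = 0.0246, median log2 change -0.52), a call lost with an estimated correlation (adjusted p = 0.127). Of the 242 tested features within 10 of a chromosome end, 110 fell and 56 rose at pH 8 (camera adjusted p = 0.0246, adjusted p = 0.441 with an estimated correlation). Both lists were set after the IDs were seen. Novel_proteincoding40 and Novel_proteincoding41 were among the newly annotated features called lower at pH 8 (log2 -3.67 and -3.15), and these calls rested on 1 library. Without pH 4 replicate 2 their log2 changes were -0.45 (SE 0.290, adjusted p = 0.199) and -0.45 (SE 0.361, adjusted p = 0.290), and 20 newly annotated features fell and 10 rose. That library had 10.9 CPM of the CaglfMp features, against 0.249 and 1.01 CPM in the other 2 at pH 4.

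The second question was which transcripts responded to nitrosative stress. CAGL0D02640g rose 223-fold with GSNO, from 1.43 ± 0.130 to 322 ± 6.15 CPM (log2 7.80, SE 0.0841, edgeR adjusted p = 4.74e-15). CAGL0D02662g rose from 1.55 ± 0.259 to 323 ± 5.37 CPM (log2 7.73, SE 0.0821, adjusted p = 4.74e-15). The levels of these features differed little from each other in any condition (126 and 128 CPM in M199 pH 4, 88.8 and 90.4 CPM in M199 pH 8), and whether they share reads could not be tested here. Both were also higher in M199 pH 4 than in YPD (log2 6.45 and 6.39). Among the polyA-selected libraries they were thus low in YPD alone. A level above that of YPD was not particular to GSNO, although it was highest there. CAGL0M03465g fell from 6431 ± 298 CPM in YPD to 3.44 ± 0.490 CPM with GSNO (log2 -10.87, SE 0.293, adjusted p = 1.92e-12). CAGL0H04939g fell from 2479 ± 87.1 to 2.53 ± 0.552 CPM (log2 -9.95, SE 0.179, adjusted p = 6.97e-14). CAGL0M03465g and CAGL0H04939g also stood low in M199, at 9.12 and 5.26 CPM at pH 4 and 5.35 and 5.63 CPM at pH 8. Among the polyA-selected libraries they were thus high in YPD alone, so their low level was not particular to GSNO. In all, 2045 features rose and 2392 fell with GSNO, 1237 and 1316 of them at least 2-fold, and 110 and 75 at least 16-fold. A fit of only the 6 libraries compared gave 2278 and 2208, so the excess of falling features depended on the libraries fitted. The median absolute change of the called features was 1.197 on the log2 scale. In the unselected libraries CAGL0D02640g had 5197 counts with GSNO and 254 without. CAGL0M03465g had 71 and 60 counts there, and CAGL0H04939g 8 and 3, so the falls of the latter features were not seen in that pair. Of the newly annotated features, 17 rose and 18 fell with GSNO, and of the features near chromosome ends 100 rose and 100 fell. Neither list passed the camera test (adjusted p = 0.992 for each).

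**Figure D1:**
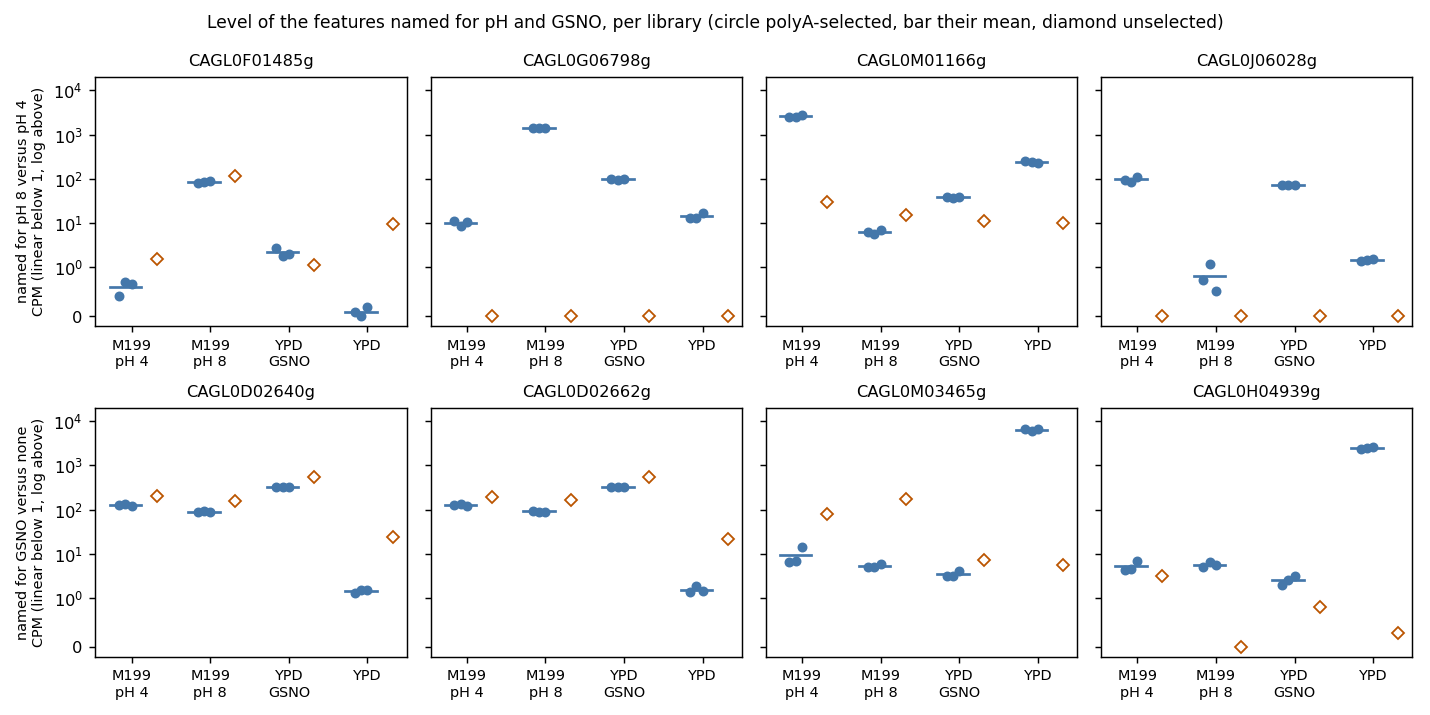
CPM of the 8 features named for the pH comparison (upper panels) and the GSNO comparison (lower panels) in each library, on an axis that is linear below 1 and logarithmic above. Circles are polyA-selected replicates, bars their means and diamonds the unselected library, whose CPM leaves out Novel_proteincoding40 and 41. CAGL0M03465g stood at 6431 CPM in polyA-selected YPD and at 5.60 CPM in the unselected YPD library.

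The media themselves were compared through M199 pH 4 and YPD, the reference condition of each experiment. CAGL0I06050g was 541-fold higher in M199 pH 4, at 14369 ± 3035 CPM against 26.6 ± 2.86 CPM in YPD (log2 9.08, SE 0.179, edgeR adjusted p = 9.50e-14). CAGL0I08613g stood at 1277 ± 385 against 1.00 ± 0.278 CPM (log2 10.24, SE 0.290, adjusted p = 2.41e-12). Both fell at pH 8, to 3270 and 287 CPM (log2 -2.14 and -2.15), and rose with GSNO (log2 4.88 and 3.66). CAGL0M03465g was lower in M199 pH 4 than in YPD, at 9.12 ± 4.30 CPM (log2 -9.51, SE 0.270, adjusted p = 2.53e-12), as it was with GSNO. In the unselected libraries the 2 features higher in M199 pH 4 were higher too, with 9888 counts of CAGL0I06050g in M199 pH 4 and 287 in YPD (15236 and 26.8 CPM) and 664 and 293 of CAGL0I08613g (1023 and 27.4 CPM). CAGL0M03465g went the other way there, with 51 counts (78.6 CPM) in M199 pH 4 and 60 counts (5.60 CPM) in YPD. CAGL0H06633g stood at 12.3 ± 4.98 CPM in M199 pH 4 and at 6367 ± 499 CPM in YPD (log2 -9.05, SE 0.274, adjusted p = 4.46e-12), and had 0 counts in the unselected libraries of both conditions. In total 2290 features were higher and 2295 lower in M199 pH 4, 1518 and 1357 of them at least 2-fold. Medium, preculture and pH differed together in this comparison. Against each of the other 3 conditions, 746 features were at least 2-fold higher and 886 at least 2-fold lower in YPD. The same counts were 184 and 94 for M199 pH 4, 58 and 107 for M199 pH 8, and 161 and 226 for GSNO.

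The pH effect and the GSNO effect, which share no library, ran in opposite directions more often than in the same one. Of the features called, 1306 rose at pH 8 and fell with GSNO, against 794 for independent lists, and 1069 fell at pH 8 and rose with GSNO, against 683. In a fit of all 16 libraries these were 612, against 284, and 370, against 248. Features that rose in both numbered 264, against 679, and features that fell in both 422, against 798. Among calls of at least 2-fold, 287 rose at pH 8 and fell with GSNO, against 92.8, and 171 did the reverse, against 104. At that threshold 20 rose in both, against 87.2, and 95 fell in both, against 111. The deficit of features that fell in both was thus small among the larger changes. Across the 5150 features, which are not independent replicates, Pearson's r between the effects was -0.322 and Spearman's rho was -0.498. By the edgeR test of the difference itself, the pH effect lay above the GSNO effect for 2270 features and below it for 2118 (2157 and 2230 with DESeq2 size factors), of which 1510 and 1490 differed at least 2-fold.

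The unselected libraries were compared with the polyA-selected ones across all conditions. Novel_proteincoding40 and Novel_proteincoding41, singled out after their values were seen, took 93.4% of the counts in the unselected M199 pH 4 library (exact 95% interval 93.39% to 93.42%) and 93.8% in the unselected pH 8 library (93.78% to 93.81%). They took 0.0453% and 0.161% in the unselected GSNO and YPD libraries. In the polyA-selected libraries their share was 0.0584% to 0.239%, except for 1.92% in pH 4 replicate 2. The other features were left with 648988 and 531920 counts in the unselected M199 libraries. The 11 CaglfMp features had 3314 and 1414 counts in the unselected M199 pH 4 and pH 8 libraries, 2 and 3 in the unselected GSNO and YPD libraries, 211 in pH 4 replicate 2 and 0 to 13 in the other polyA-selected libraries. All 5 CaglfMp features that passed the filter over 16 libraries were called higher in the unselected libraries, calls that rested on the unselected M199 libraries.

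**Figure D2:**
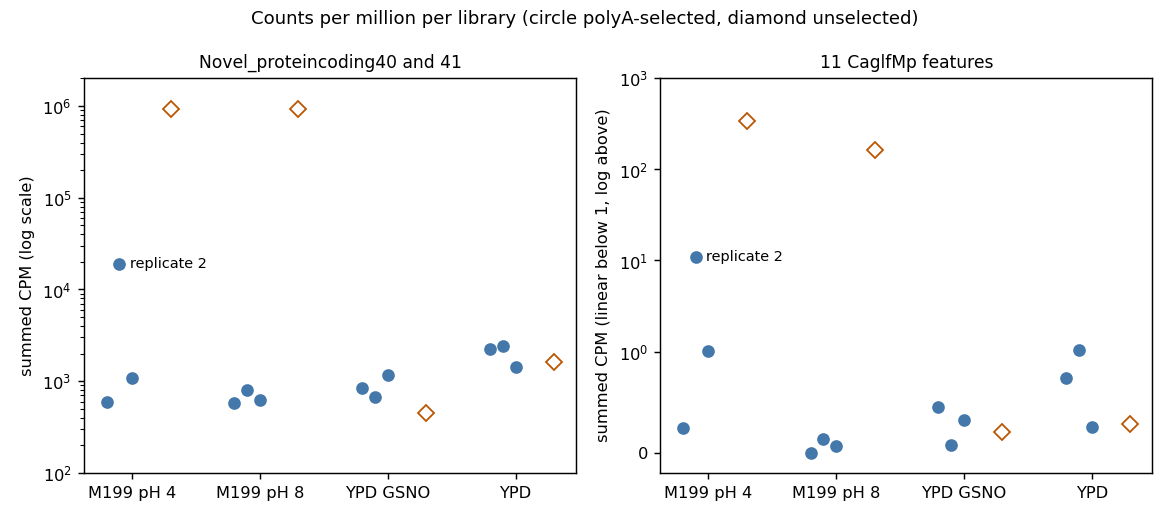
Summed CPM of Novel_proteincoding40 and 41 (left, log axis) and of the 11 CaglfMp features (right, linear below 1 and logarithmic above) in each of the 16 libraries, with circles for polyA-selected and diamonds for unselected libraries. The unselected M199 libraries lie at 934086 and 937979 CPM on the left, and pH 4 replicate 2 lies above the other polyA-selected libraries in both panels.

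With condition as a covariate, 1243 features were higher and 1412 lower in the unselected libraries, 408 and 740 of them at least 2-fold. This fit takes 1 effect of the kind of library for all conditions, so its values are averages over them. The unselected libraries did not all depart alike, as the CaglfMp counts show (3314 and 1414 in M199, 2 and 3 in GSNO and YPD). Which direction held more features changed with the size factors (1418 higher and 1281 lower with those of DESeq2). CAGL0J01800g stood at 23.7 to 40.3 CPM in the unselected libraries and at 0.125 to 0.996 CPM in the polyA-selected ones (log2 5.73, SE 0.268, edgeR adjusted p = 2.72e-10). CAGL0G02871g ranged from 1.59 to 693 CPM in the unselected libraries and up to 0.149 CPM in the others (log2 11.38, SE 1.03, adjusted p = 5.25e-07). CAGL0M03861g and CAGL0K10164g had 0 counts in the unselected libraries, against means of 2916 and 1820 CPM in the polyA-selected ones. At the polyA-selected level of each condition the 4 unselected libraries would have held 67172 and 63946 counts of them, so with an upper limit of 3 counts over the 4 libraries they were at least 22390-fold and 21315-fold lower, bounds set mostly by the deeper GSNO and YPD libraries. Among the 47 newly annotated features, 26 were lower and 8 higher in the unselected libraries. Selection, read layout, strand information and culture differed together between the kinds of library.

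Features called at pH 8 in the polyA-selected libraries mostly kept their direction between the single unselected libraries. Features without a read in either unselected library show no direction and were left out, 55 called higher and 79 called lower at pH 8, and 71 and 57 with GSNO. Of the remaining features called higher at pH 8, 86.7% were higher there (exact 95% interval 85.0% to 88.3%), and of those called lower, 85.7% were lower (83.9% to 87.4%). For GSNO the shares were 63.6% of the features called higher (61.4% to 65.7%) and 63.0% of those called lower (61.0% to 65.0%). For M199 pH 4 with YPD they were 60.3% (58.2% to 62.4%) and 65.8% (63.8% to 67.8%). The intervals treat features as independent. Across features the log2 changes in the 2 kinds of library correlated at r = 0.789 for pH and 0.221 for GSNO.

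**Figure D3:**
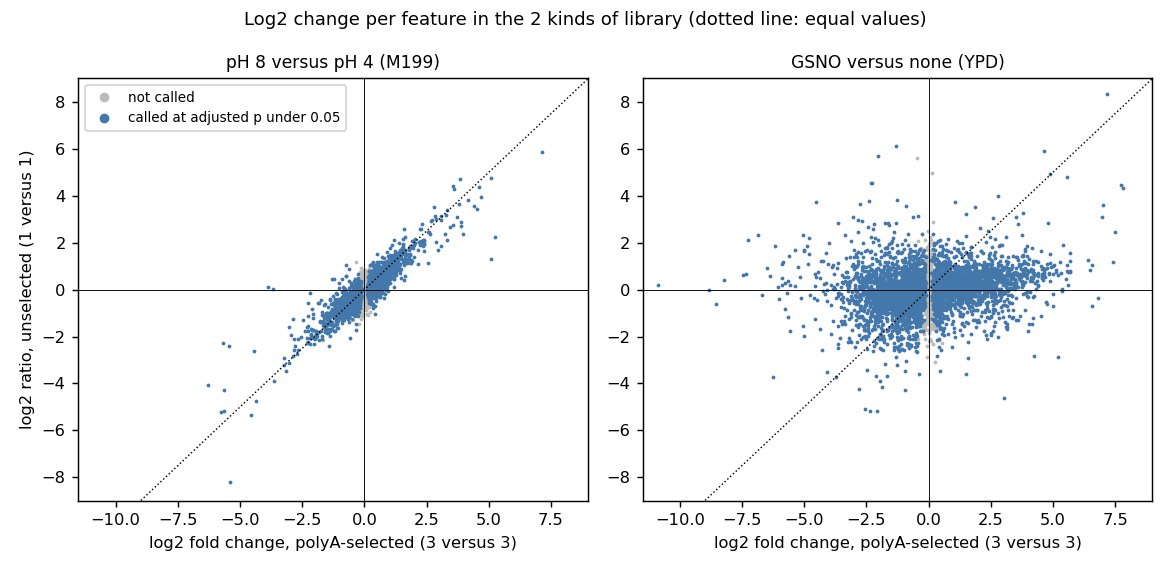
Log2 fold change in the polyA-selected libraries (x axis) against the log2 ratio of the single unselected libraries (y axis) for features with at least 50 counts in the unselected pair, for pH (left) and GSNO (right). Blue points were called in the polyA-selected libraries, and the dotted line marks equal values. With this minimum, r across features was 0.888 for pH and 0.224 for GSNO.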

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

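The tests of another expression state in the unselected YPD library, of polyA selection as the sole setting of the level of Novel_proteincoding40 and 41, of unselected RNA in pH 4 replicate 2, and of lost reads except that with features kept in the GSNO library, were chosen after the results were seen. So were the fit over 16 libraries with a mean per condition and library kind, the thinned libraries, the shuffled levels, the correlations with and without centring, the values per CaglfMp feature, and the M199 libraries as controls.

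The GSNO effect differed between the kinds of library for 3569 of 5185 features and the M199 pH 4 against YPD effect for 3088, by edgeR's test of the difference with 1 unselected library per condition, whose spread is taken from the polyA-selected replicates. The pH effect differed for 41, in a pair with fewer counts. With the unselected GSNO and YPD libraries thinned to the counts of the M199 pair (5 draws), 2491 to 2535 and 2669 to 2688 features differed, against 41. A difference between single libraries and one between the kinds of library cannot be separated here. CAGL0M03465g and CAGL0H04939g were among the features whose fall with GSNO was not seen in the unselected pair. Several explanations were tested for the lower repeat of GSNO effects. Shallow counts are argued against, since 67.2% of called-lower features with at least 1000 counts were also lower in the pair (exact 95% interval 64.6% to 69.7%), where at least 80% would be needed. The share was not below the 65% set beforehand for exclusion, so this rests on the interval lying below 80% and on depth, since the GSNO and YPD pair held 9727060 and 10706342 counts against 648988 and 531920 in the M199 pair after the 2 abundant features. An effect of the kind of library that is the same in all conditions cancels in these ratios and was not tested. Loss of reads in both unselected libraries is argued against by a share of 71.1% (68.9% to 73.2%) among called-lower features kept, on average over the 2, at 0.5 times their polyA-selected level or more. Among those kept in the unselected M199 libraries, which are not part of the pair, it was 62.9% (60.8% to 65.0%). The share was 62.1% among features kept in the GSNO library and 80.4% among those kept in the YPD library, choices that act on the ratio itself and decide nothing, so a loss in the unselected YPD library alone stays open. What also stays open is that the unselected YPD library may hold another expression state than YPD replicates 1 to 3. Its log2 ratio to unselected GSNO correlated at r = 0.241 with that of polyA-selected YPD, and at 0.678 and 0.531 with those of M199 pH 8 and pH 4, across 4128 features. All these ratios subtract GSNO, which raises each r: with the unselected YPD levels shuffled among features of like level, the mean r was 0.404, 0.480 and 0.393. The unselected M199 pH 4 and pH 8 libraries, treated the same way, correlated best with their own condition (0.831 and 0.848). After centring each feature over the 4 conditions, the unselected M199 pH 4, pH 8 and GSNO libraries each correlated best with their own condition (r = 0.615, 0.533 and 0.760), and the unselected YPD library correlated at 0.0534 with its own, 0.113 with GSNO, -0.000821 with M199 pH 8 and -0.203 with M199 pH 4, and without centring at 0.485 with its own, 0.813 with M199 pH 8, 0.803 with GSNO and 0.783 with M199 pH 4, where each of the other unselected libraries again correlated best with its own (0.821, 0.816 and 0.947). Without centring it thus lay further from its own condition than from the other 3, with none of the 3 far ahead, and with centring this ranking did not hold. Which of the YPD libraries departs from the labelled condition, and whether the cultures differed, was not tested.

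The CaglfMp features and Novel_proteincoding40 and 41 gave a signal in the unselected M199 libraries above that in the polyA-selected libraries. The 2 newly annotated features took 93.4% and 93.8% of the counts at pH 4 and pH 8. The CaglfMp features summed to 337 and 165 CPM of all counts, and to 5106 and 2658 CPM with the 2 newly annotated features left out of the total. Whether polyA selection alone set this level could not be decided. In the unselected GSNO library the CPM of Novel_proteincoding40 and 41 was 0.674 times that of the lowest polyA-selected GSNO library. That would count against selection alone only if this library was made without selection, as labelled. Its level of both signals was like that of polyA-selected libraries, and the tables cannot check the label. In pH 4 replicate 2 the excess over replicates 1 and 3 came to 1.96% of the unselected pH 4 level for Novel_proteincoding40 and 41 and to 3.05% for the CaglfMp features. The ratio of these shares, 1.56, is what a small share of unselected RNA in that library would give, but the CaglfMp features with at least 50 counts in the unselected library did not all agree. CaglfMp09, with 20 counts in replicate 2 and 55 in the unselected library, came to 17.1% (9.90% to 27.1%), and the other 5 to between 1.84% and 3.34%, so this stays open. Why the unselected GSNO and YPD libraries lack both signals stays open, since medium and library preparation cannot be separated there, and no biological explanation was tested.

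The pH effect and the GSNO effect differed for 4388 features by edgeR's test of the difference. Of 100 assignments of the 12 libraries to 4 groups of 3, only the real one (1 of 100) called as many, and the highest of the others called 617. The other assignments mix conditions within groups, which raises the spread, so fewer calls were to be expected from them. These draws therefore cannot exclude chance and do not test the difference between the 2 effects itself.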

How the results depend on the processing

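The counts at 1000 or more reads, the calls kept without a read, the fit of 8 libraries, the left-out replicates of the correlation, and all tests of the 2 sets were chosen after the data were seen. The 12 log2 fold changes of the features named in the pH, GSNO and medium comparisons kept their direction and their call in all 156 alternative values. Counts of called features stayed within 1.5 times the main count under the other size factors, DESeq2, both filters, RPKM with limma, thinned counts and each left-out replicate. Without pH 4 replicate 3 the pH calls numbered 1931 higher and 1943 lower. The balance of directions turned for the unselected libraries, with 1568 higher and 1357 lower with DESeq2, 1186 and 958 in the 8 YPD and GSNO libraries, and 1556 and 1173, or 1540 and 1193, without unselected pH 4 or pH 8. With limma on log2(RPKM + 1) and a mean RPKM of at least 1, 59.7% of the pH calls were higher, against 49.9% with edgeR, and the median of all features shifted to 0.08. DESeq2 moved the pH balance the other way, to 1617 higher and 1833 lower, so this balance depended on the scaling. With all 16 libraries and a library term, the pH calls fell to 792 higher and 746 lower, of which 1535 were also called with 12 libraries, and the overlaps of opposite direction fell to 612 and 370. That fit adds the unselected M199 libraries, whose other features hold 648988 and 531920 counts. At least 2-fold changes numbered 363 and 435 for pH, 1237 and 1316 for GSNO, 1518 and 1357 for M199 pH 4 with YPD, and 408 and 740 for the unselected libraries. Fewer features pass a second threshold by construction. Pearson's r between the pH and GSNO effects was -0.308 without a filter, -0.349 with all 16 libraries, -0.498 as Spearman's rho, and between -0.329 (without YPD replicate 3) and -0.321 with 1 replicate left out.

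The share of calls repeated by the unselected pair moved with its filters. For pH 8 it was 89.6% (higher) and 91.2% (lower) at 50 or more counts in the pair, 98.3% and 92.3% for calls of at least 2-fold, and 91.1% and 97.2% at 1000 or more counts. For GSNO it was 69.3% for 2-fold calls higher and 67.2% for calls lower at 1000 or more counts. Other GSNO shares hardly moved, with 62.5% for 2-fold calls lower and 64.4% for calls higher at 1000 or more counts. At 50 or more counts they were 64.4% (higher) and 62.7% (lower). For M199 pH 4 with YPD it was 64.9% for 2-fold calls higher, and 51.2% (higher) and 74.4% (lower) at 1000 or more counts. The cause of these shifts was not tested. Keeping features without a read among the calls lowers the share by construction, to 83.9% and 81.8% for pH 8, 61.4% for GSNO calls higher and 63.6% for M199 pH 4 calls lower.

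The replicate numbers did not pair the libraries across all conditions. Of 18 pairs with the same number, 6 had a correlation of deviations over 0.1 (range -0.673 to 0.552), and 0 of 12 libraries were closest to their own number in every other condition. For replicates 1, 2 and 3 it was 0.552, -0.197 and 0.473 between pH 4 and pH 8. Between GSNO and YPD it was -0.030, -0.194 and -0.290. Pairing within M199 alone thus stays open. With the replicate block, 1653 and 1648 features were called for pH, 2013 and 2365 for GSNO, and 2272 and 2278 for M199 pH 4 with YPD, and 3290, 4371 and 4546 of the main calls were kept. The camera calls of both sets at pH 8 were kept under the block (adjusted p = 0.0231) and lost with an estimated correlation (0.127 and 0.441), and that of features near chromosome ends also with 20 in place of 10 features per end (0.0755). The planned tests of gene lists were not run, since no list had a member that passed the filter in the 12 polyA-selected libraries they use.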

Other observations

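The tests in the first paragraph and the counts of features lost in the unselected libraries were chosen after the results were seen. The GSNO effect and the M199 pH 4 effect, both measured against the same YPD libraries, resembled each other. Of the features called, 1681 were higher in both, against 909 for independent lists, and 1865 were lower in both, against 1066. Across features r was 0.828. With all 12 libraries, YPD included, simulated around the YPD means, unchanged groups gave a mean r of 0.530 over 20 draws. In these draws 0 features were called alike in both at an edgeR adjusted p under 0.05. The simulation covers sampling noise of a shared reference, and a departure of the real YPD libraries is not part of it. The covariance of the effects was 3.14, against 0.0134 in the simulation. With 3 YPD libraries no split kept 2 in each part, and part of the overlap above independent lists can come from the shared YPD libraries.

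Features at 0 in the unselected libraries included abundant ones. Of the 4930 tested features with a mean of at least 10 CPM in the polyA-selected libraries, 134 (2.72%) had 0 counts in each of the 4 unselected libraries, among them CAGL0G06798g and CAGL0J06028g. Their median level in the polyA-selected libraries was 99.9 CPM and their highest 3391 CPM. In the polyA-selected libraries 77 of them were called in the pH comparison and 114 in the GSNO comparison, calls that the unselected pairs cannot bear on. Shallow counts are argued against, since at the polyA-selected level the median expected count in the unselected GSNO library was 870. Reads shared with a neighbouring feature and discarded where strand was not recorded may contribute. The 237 counted neighbours had a median log2 ratio of unselected to polyA-selected level of 0.0307 in YPD and GSNO, against 0.239 for the other features, and 6 of 1000 random draws lay as low. The predicted bound, below every draw, was missed. A value within the draws had been set beforehand as counting against this explanation, and it was left open only after the value was seen, since so few draws lay as low. No biological explanation was tested.

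Features next to each other in the order of their IDs changed alike to a small degree. Over 5090 adjacent pairs r was 0.0875 for the GSNO effect and 0.0744 for the pH effect, above the highest of 1000 shuffles within chromosomes (0.0457 and 0.0444). CAGL0D02640g and CAGL0D02662g are 1 such pair, and shared regulation and shared reads are candidate explanations that the tables do not separate. The table also holds 31 features with a suffix on a split ID, which were kept in this order. Features that share an ID apart from the suffix can thus be adjacent, and r without them was not computed. Features within 10 of a chromosome end did not change more often: 47.9% changed at least 2-fold with GSNO, within the range of 10000 lists matched on mean CPM (44.2% to 56.2%), and 19.0% at pH 8 (13.6% to 22.3%).

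Other splits of the libraries were fitted for each comparison with edgeR. For 3 against 3 libraries there are 10 splits, too few to give a share under 0.05. In fits of the 6 libraries compared, the real split called 3110 features for pH, 4486 for GSNO and 4412 for M199 pH 4 with YPD, each the largest (1 of 10). The highest of the other splits called 0 in each comparison at an adjusted p under 0.05 and 464, 5 and 69 at an unadjusted p under 0.05. For the unselected libraries, 100 choices of 1 library per condition were fitted. Only the real choice (1 of 100) called 2655 features or more, and the highest of the others called 965. The other choices leave unselected libraries among the polyA-selected ones, which raises the spread. Fewer calls were to be expected from them, so these draws cannot exclude chance.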
